A study of Homo sapiens with 12 samples.

How the data were processed

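RNA-seq and 3' end-seq libraries were made from WA01-derived neurons after 7 days of scrambled or TDP-43 shRNA, with 3 libraries per group and 12 in all. Per the labels' protocols, RNA was extracted with trizol and treated with DNase, RNA-seq libraries were made with a stranded total RNA kit for low input, and 3' end-seq libraries with a QuantSeq REV kit. QuantSeq REV primes on poly(A), so priming at internal A-rich stretches can look like a polyadenylation site. No genome sequence was used here, so that could not be tested. The submitters' processing notes name fastp, Salmon, DESeq2, STAR and SAMtools and the hg38 build, without versions or roles. The callers of polyadenylation changes and of cryptic sites are not given in the sources used here.

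The values used were the authors' own comparisons in 5 deposited tables, with no value per library. The changes of the polyadenylation usage index are a deposited score whose scale is not stated; the RNA-seq score exceeds 1 for some genes, so it is no difference of fractions. The changes of intron share are a deposited score as well, rounded to 3 decimals by the authors and summing to 0 within a cluster. The p-values are adjusted p-values that the authors deposited, one per gene or per cluster; in 3' end-seq 150 were given as exactly 0. The usage of each cryptic site is a deposited fraction with 1 value per group, printed here as a percent, so replicates were pooled or averaged by the authors and the denominator is not stated. The number of introns per cluster is a whole number in the deposited table. All tables list changed items only, at adjusted p up to 0.05 where one is given, so the number of items tested is not known. The depth is unknown, and no interval that needs it was computed.

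A gene table with 6 columns of per-sample values was not used. Its columns are numbered 1 to 6 after the assay name, and no label ties a number to a sample. Gene expression, the level of TARDBP, gene list tests on expression, and the relation of expression to polyadenylation or splicing, which were planned, were therefore not run. The direction tests were fitted to the deposited lists in place of tests on values per library.

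In 3' end-seq, the authors' labels longer and shorter and their rising and falling sites were used as deposited. Rising means rising in the knockdown, since 199 cryptic sites with higher usage in the knockdown column were rising sites and 0 were falling sites. For RNA-seq polyadenylation and for splicing the subtracted group is not stated, and positive values were read as higher in the knockdown. The reading rests on the match with the 3' end-seq directions for RNA-seq polyadenylation, and on the STMN2 junction for splicing. Gene symbols were taken from the tables. Older symbols were matched through the synonyms of the RefSeq gene table (GRCh38.p14): 102 symbols in the splicing table and 19 in the RNA-seq polyadenylation table, with 15 and 1 left unmatched and kept as given. The 3' end-seq table left 127 genes unnamed; those without a symbol in the reference keep their identifier. Coordinates are those of the authors' tables in hg38. A site was placed inside, before or past the RefSeq gene of the same symbol and chromosome; 2051 of 2083 matched 3' end-seq genes (98.5%) had a site inside. The cryptic table repeated 2 of its 459 lines, which were counted once.

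Shares of genes or introns were given with 95% exact (Clopper-Pearson) binomial intervals, and directions were tested with two-sided exact binomial tests against equal shares. Associations were tested with two-sided Fisher's exact tests, and with a Mantel-Haenszel odds ratio where stratified by distance. Differences in distance and correlations across genes were tested with 100000 permutations. Families of tests were adjusted by Benjamini-Hochberg. All of these treat genes, sites or introns as units, which are not independent replicates. No enrichment was tested, because the genes that could have been called are not known. For overlap, the number of jointly tested genes at which the overlap equals chance was given in its place. A junction was counted as near a site when it ended up to 1000 nt upstream of it on the same strand. The functions for binomial intervals, Fisher's test, the Mantel-Haenszel odds ratio and junctions near a site were first tested on simulated data with known answers. The Benjamini-Hochberg adjustment was tested on a worked example. The permutation tests, the placement in RefSeq genes and the matching of symbols were not tested in this way. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

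Genes were named by a rule fixed before the data were examined: the 8 with the largest change in each direction of each table (16 by knockdown usage for cryptic sites), members of the reported target lists and of the ALS and FTD list, and up to 4 members with the smallest p per list. For the deposited tables, listed members of any list were eligible, which is wider than the rule, and the examples given were chosen among them after their values were seen. The highest cryptic sites per feature were added after the data were examined. Y-linked genes were not named, and 1 member of the ALS and FTD list is not reported here. There were 25 gene lists fixed before the data were examined, 16 of pathways and complexes and 9 of cell type markers; they were counted in each table, and the split of longer and shorter was tested in the 4 lists with at least 5 members in the 3' end-seq table. Alternatives were stricter adjusted p-values (0.01 and 0.001), larger effects, larger intron changes (0.1 and 0.2), and, added after the data were examined, sites at least 200 nt apart, genes matched in RefSeq, strata of distance, repeated lines kept, knockdown usage of at least 20%, named sites only, and sites over 100 nt past a gene end. A site was otherwise counted as past the end at any distance.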

Results

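The series measured RNA from cortical neurons made from WA01, an established human embryonic stem cell line, by forced expression of the transcription factor NGN2. The neurons received either a scrambled short hairpin RNA or a hairpin against TDP-43 for 7 days. TDP-43, encoded by TARDBP, is an RNA-binding protein that is lost from the nucleus of neurons in amyotrophic lateral sclerosis (ALS) and frontotemporal dementia (FTD). The series asked how its loss changes the choice of polyadenylation site, the place where a transcript is cleaved and given its poly(A) tail. There were 12 libraries, 6 of stranded total RNA-seq and 6 of 3' end-seq (a QuantSeq REV assay, which reads the last bases of transcripts). Each assay had 3 scrambled and 3 TDP-43 shRNA replicates. The labels do not say whether replicates came from separate cultures, so the authors' p-values may measure technical spread. The values below come from 5 tables of the authors' own comparisons, which list changed genes, sites and introns without a value per library. The depth is unknown, no spread between replicates can be given, and the adjusted p-values are the authors'. The level of TARDBP RNA was not analysed here, so the strength of the knockdown is not known from these values, and TARDBP was not among the genes listed in the 5 tables.

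Transcripts of most genes with a polyadenylation change in 3' end-seq ended farther downstream after TDP-43 knockdown. The authors' deposited table held 2220 genes, each with a site whose use fell and a site whose use rose, and called 1881 longer and 339 shorter. NEFL, which encodes the neurofilament light chain, was longer with a change in usage index of 0.315 in the authors' deposited table. Its use moved 471 nt, from position 24951428 to position 24950957 on the minus strand of chromosome 8 (hg38), both inside the RefSeq gene. SFPQ, a nuclear RNA-binding protein, was longer by 0.314 and the kinase gene MARK3 by 0.425 in the authors' deposited table. The share called longer was 84.7% (95% exact binomial interval 83.2 to 86.2, two-sided exact binomial p = 3.26e-258 against equal shares). Genes are not independent replicates, so that p-value describes the list and not the libraries. The scale of the usage index is not stated in the sources used here, and the smallest change listed was 0.10 in size.

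The genes at the ends of the authors' deposited table were of several kinds. The largest changes among genes called longer were those of ENSG00000273432 at 0.797, ANKRD29 at 0.763, ENSG00000269072 at 0.757 and C17orf97 at 0.711, as given in the authors' deposited table. PRKCQ-AS1 at 0.666, LINC01023 at 0.655, ZFTRAF1 at 0.654 and ENSG00000266947 at 0.632 followed in the authors' deposited table. Of these 8, only ANKRD29 had both sites inside its RefSeq gene. C17orf97 and the genes given by identifier had no RefSeq gene to check. The rising sites of PRKCQ-AS1 and LINC01023 lay past the RefSeq end, and the falling site of ZFTRAF1 lay before the RefSeq start. Among genes called shorter, CEACAM21 had the largest change in the authors' deposited table at -0.615. It was followed in the authors' deposited table by GSTO2, a glutathione transferase, at -0.569 and by AUTS2, a gene linked to neurodevelopment, at -0.567. TMEM147-AS1 at -0.546, POC1B-AS1 at -0.545, BDH1 at -0.539, SCN9A at -0.538 and PIGL at -0.527 came next in the authors' deposited table. SCN9A encodes a voltage-gated sodium channel and PIGL an enzyme of glycosylphosphatidylinositol anchor synthesis. In SCN9A, on the minus strand of chromosome 2, the rising site at 166221392 lay 23004 nt upstream of the falling site at 166198388 in the authors' deposited table.

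The falling and the rising site lay farther apart on the genome in shortened genes than in lengthened ones. Distances here are genomic and include any intron between the sites, as in AUTS2 at 1118275 nt, so they are not lengths of transcript. The median distance between the falling and the rising site was 2555 nt in genes called longer and 9829 nt in genes called shorter, computed from the authors' deposited table. The mean log10 distance was 3.44 in longer and 3.91 in shorter genes (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). Sites over 10000 nt apart were found in 381 of 1881 longer genes (20.3%) and 167 of 339 shorter genes (49.3%, odds ratio 3.82, two-sided Fisher's exact p = 6.24e-27). The share called longer was 92.0% of the 873 genes with sites between 1000 and 5000 nt apart and 69.5% of the 548 genes with sites over 10000 nt apart.

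**Figure D1:**
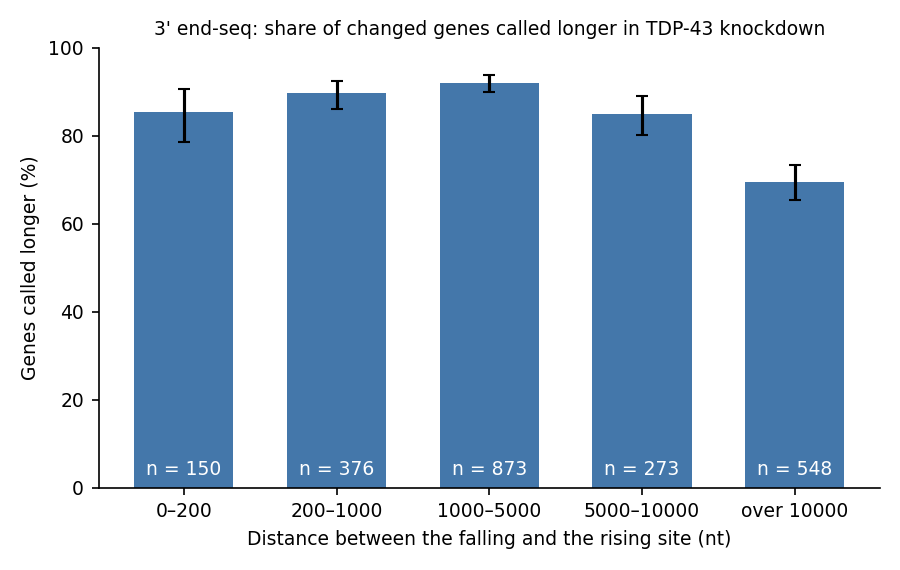
The bars show the percentage of genes in the authors' deposited 3' end-seq table that were called longer (y axis). The x axis is the genomic distance in nucleotides between the falling and the rising site, introns included. Error bars are 95% exact binomial intervals over genes and n is the number of genes; the share was 92.0% at 1000 to 5000 nt and 69.5% at over 10000 nt.

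Several gene groups fixed before the data were examined had members in the 3' end-seq table. Of 14 genes reported elsewhere as polyadenylation targets of TDP-43, 3 were longer (MARK3, NEFL and SFPQ) and 3 were shorter (STMN2 at -0.391, SMC1A at -0.197 and CNPY3 at -0.102) in the authors' deposited table. That list was drawn from what was known of this subject, so its members are not independent evidence. ELK1 and SIX3, also on that list, were not among the genes listed from 3' end-seq. Each had a cryptic site, one little used in control neurons, in an extension past the 3'UTR (described below). Of the 160 cryptic sites of that kind, 0 were rising sites in 3' end-seq, so the split of 3 and 3 leaves them out. All 7 of the 25 cleavage and polyadenylation factors that the authors' deposited table listed were longer. They included CSTF3 at 0.498, SSU72 at 0.434, RBBP6 at 0.359 and CPSF6 at 0.259 in the authors' deposited table, genes whose products act in cleaving the transcript end or on the polymerase that makes it. WDR33 at 0.219, PCF11 at 0.212 and CSTF2T at 0.164 were the others in the authors' deposited table. Of 40 neuronal and hnRNP RNA-binding proteins, 5 were longer (with TIAL1 at 0.281 and CELF2 at 0.160) and 1 was shorter (RBFOX1 at -0.182) in the authors' deposited table. Among 27 voltage-gated ion channel genes 3 were longer, including CACNA1C at 0.232, and 2 were shorter, SCN9A and KCNH7 at -0.106, in the authors' deposited table. Among the ALS and FTD genes, CFAP410 was longer at 0.134 in the authors' deposited table. In the 4 lists with at least 5 members in the table, the split of longer and shorter was compared with that of the other genes by two-sided Fisher's exact test. None passed 0.05 after Benjamini-Hochberg adjustment over the lists: the adjusted p was 0.198 for the polyadenylation targets (unadjusted 0.0494), 0.340 for ion channels, 0.805 for cleavage factors and 1 for RNA-binding proteins.

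Polyadenylation changes called from RNA-seq went mostly one way. The authors' deposited table held 841 genes, of which 799 were called distal and 42 proximal. TCF25 at 3.85, LGALS3BP at 3.29, APBB3 at 3.19 and PPP1R14A at 3.16 led the distal genes in the authors' deposited table. SUSD2 at 3.09, AP2M1 at 3.04, AP1M1 at 2.78 and PCED1A at 2.78 came next in the authors' deposited table; AP2M1 and AP1M1 encode subunits of clathrin adaptor complexes. GPR62 at -1.9, SHPK at -1.47, the axon guidance receptor gene ROBO1 at -1.25 and MYO19 at -1.17 led the proximal genes in the authors' deposited table. KLC3 at -1.12, RPS6KA2 at -1.06, the transcription factor gene FOXO3 at -1.05 and PPIA at -0.966 followed in the authors' deposited table. Some of these changes exceed 1, so the index is on another scale than a difference between fractions and its values are not set against the 3' end-seq values by size. The distal share was 95% (95% exact binomial interval 93.3 to 96.4, two-sided exact binomial p = 2.51e-182 over genes, which are not independent replicates). The table does not state which group was subtracted. Distal is read here as more distal use in the knockdown because that reading matches most 3' end-seq directions in the shared genes, so the direction is not an independent result of RNA-seq.

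By group, 4 of the 34 ALS and FTD genes were listed from RNA-seq and all 4 were distal. They were FIG4 at 1.56, DCTN1 at 1.46, C9orf72 at 0.522 and VAPB at 0.340 in the authors' deposited table. Since 95% of all genes listed from RNA-seq were distal, being all distal does not set a group apart. DCTN1 encodes a subunit of dynactin, which links cargo to the dynein motor, and FIG4 a phosphoinositide phosphatase. All 14 of the 48 ribosomal protein genes listed were distal, with RPS15 at 2.06, RPL11 at 1.47 and RPL10A at 1.37 in the authors' deposited table. The 3' end-seq table listed 3 of the same 48 genes, RPL14, RPL22 and RPS23, all longer and all among the 14. All 7 RNA-binding protein genes listed were distal, including HNRNPF at 0.873, HNRNPR at 0.774 and CELF2 at 0.674 in the authors' deposited table. DLG4, which encodes a postsynaptic scaffold protein, was distal at 1.85 and SHANK2 at 0.425 in the authors' deposited table. SYP, a synaptic vesicle protein gene, was proximal at -0.182 in the authors' deposited table and shorter in 3' end-seq at -0.157. PABPC1 at 1.12, TUBB2B at 0.641 and CYFIP2 at 0.643 were distal members of 3 further lists in the authors' deposited table (cleavage factors, neuronal cytoskeleton and reported splicing targets).

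The 2 assays, run on separate libraries, shared 234 genes. With the RNA-seq direction read as stated, 225 had the same direction (96.2%, 95% exact binomial interval 92.8 to 98.2) and 9 the opposite. The reverse reading would exchange these counts, so the 225 do not show on their own that the assays had a common direction. The association between the 2 directions does not depend on the reading (two-sided Fisher's exact p = 1.68e-08 over genes), and 90.6% would match under this reading if they were unrelated. Both tables called 218 genes longer and distal and 7 genes shorter and proximal, the latter including PPIA, RPS6KA2 and SYP. The opposite calls were 7 genes shorter and distal and 2 genes longer and proximal. The 2, MYO19 and IRX2-DT, had changes of 0.155 and 0.518 in 3' end-seq and of -1.17 and -0.786 in RNA-seq in the authors' deposited tables; IRX2-DT was chosen after its values were seen. The shared count equals what chance would give if 7975 genes could be tested in both assays; the number of genes tested is not known here, so no enrichment was tested. Across the 234 genes, which are not independent replicates, Pearson's r of the changes was 0.239 (permutation p = 3e-04) and 0.240 without the 2 genes farthest from the median. Spearman's rho was 0.0817 (permutation p = 0.214), and 0.0233 (p = 0.732) within the 218 genes called longer and distal. The directions were thus associated across genes, while no relation in the size of the change was detected within the longer and distal genes.

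**Figure D2:**
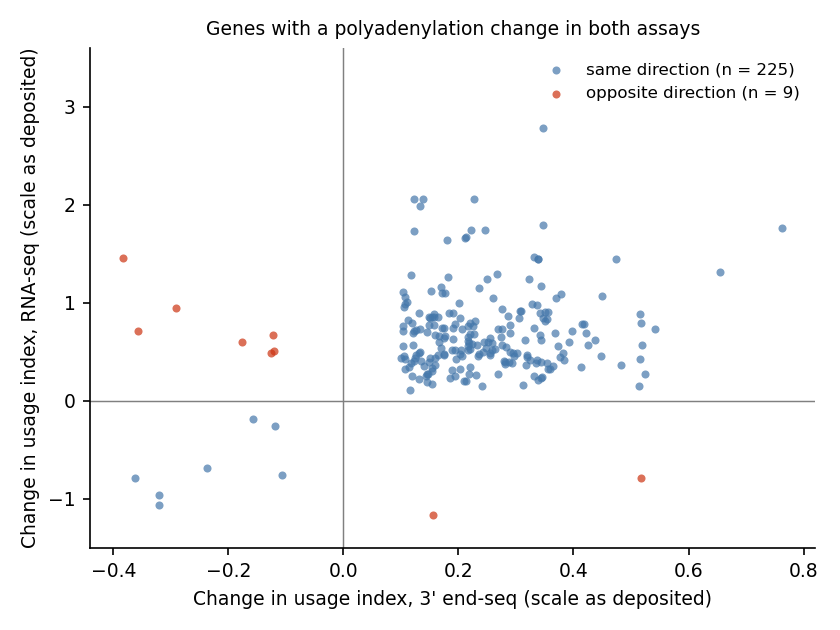
Each point is 1 of the 234 genes in both authors' deposited polyadenylation tables, with its change in usage index in 3' end-seq (x axis) and in RNA-seq (y axis), each on the scale as deposited. Blue points (225 genes) have the same direction in both assays and red points (9 genes) the opposite, with the RNA-seq direction read from its match with 3' end-seq.

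Cryptic polyadenylation sites, which were little used in control neurons, gained use in the knockdown. The authors' deposited table held 457 distinct sites, of which 439 were assigned to 423 named genes. The median usage was 3.27% in control (range 0.0207 to 5.99) and 19.1% in the knockdown (range 10.7 to 82.6), with 1 value per group. ELK1, which encodes an ETS-family transcription factor, rose from 1.90% to 78.1% in the authors' deposited table, at position 47631616 on the minus strand of the X chromosome, 3904 nt past the RefSeq end. SIX3, a homeobox gene, rose from 4.84% to 62.6% in the authors' deposited table, at position 44948084 on chromosome 2, 2013 nt past its RefSeq end. C17orf97 reached 82.6% at an intronic site in the authors' deposited table. TKFC reached 71.5%, PPIE 70.4% and the proteasome gene PSMC2 60.1% at sites past the 3'UTR in the authors' deposited table. The table gives no p-value and lists sites chosen by the authors as low in control, so the gain describes how sites were selected as well as what changed.

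By position, the authors' deposited table placed 160 sites (35.0%) in extensions past the 3'UTR, 144 (31.5%) in 3'UTRs, 129 (28.2%) in introns and 24 (5.25%) in exons. Of the extension sites, 151 lay past the RefSeq end of the named gene, by a median of 2876 nt. The sites marked as premature were exactly the intronic and exonic ones. Intronic sites with high knockdown usage in the authors' deposited table included C17orf97 at 82.6%, POC1B-AS1 at 62.5%, GSTO2 at 61.1% and AUTS2 at 60.7%. SCN9A at 60.3%, PLD5 at 60.1% and BOK-AS1 at 54.9% were others in the authors' deposited table. The C17orf97 site was the rising site of a gene called longer, and no RefSeq gene matched that name. FEM1A at 58.5% and PLPPR5 at 48.1% were the 3'UTR sites with the highest knockdown usage, and ZNF496-DT at 52.0% was the exonic one, in the authors' deposited table. SMC1A, a cohesin subunit gene, rose from 0.646% to 19.9% at a 3'UTR site, and the cleavage-factor list member SCAF4 from 2.16% to 26.3% at an extension site, in the authors' deposited table. The rising site of a 3' end-seq pair was the cryptic site itself for 199 of the 457 sites, and no cryptic site was a falling site. Genes called shorter had a cryptic site in 19.8% of 339 genes and genes called longer in 8.30% of 1880 (odds ratio 2.72, two-sided Fisher's exact p = 3.09e-09, 9.26e-09 after adjustment over 3 such tests). Because the 2 tables share sites, that comparison is not between independent measurements. Few extension sites enter it: 0 of the 160 were rising sites of a pair, against 103 of 144 3'UTR and 78 of 129 intronic sites. Of the 160, 22 lay in genes called longer and 2 in genes called shorter. By count, 156 genes called longer and 67 called shorter had a cryptic site. Rising cryptic sites in longer against shorter genes numbered 84 against 19 in 3'UTRs, 12 against 6 in exons and 34 against 44 in introns. Cryptic sites were thus found in more longer than shorter genes, except in introns. The odds ratio reflects that far fewer genes were called shorter, and does not show that cryptic sites go mainly with shortening.

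**Figure D3:**
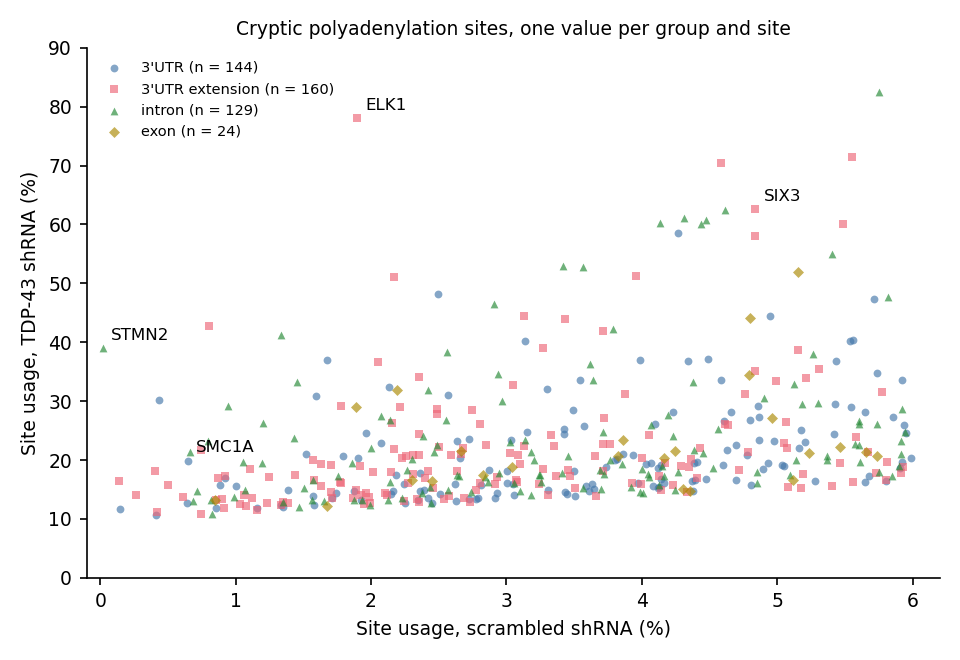
Each point is 1 of the 457 cryptic sites in the authors' deposited table, with its usage in percent in scrambled shRNA neurons (x axis) and in TDP-43 shRNA neurons (y axis), coloured by position in the gene. Control usage is at most 5.99% and knockdown usage at least 10.7% at every site; there are no error bars because the table gives 1 value per group.

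STMN2, which encodes the microtubule regulator stathmin-2, changed in splicing and polyadenylation at the same place. Its intronic site at position 79617048 on chromosome 8 rose from 0.0207% to 39.0% usage in the authors' deposited table, the lowest control usage of the 457 sites. The falling site was at position 79666156, 49108 nt downstream, and the gene was called shorter in 3' end-seq. In the RNA-seq splicing table, the intron from 79611214 to 79616822, which ends at an unannotated 3' splice site, gained 44.9 percentage points of its cluster in the authors' deposited table. The annotated introns from 79611214 to 79636802 and from 79636897 to 79641378 changed by -26.4 and -18.5 points in the authors' deposited table (cluster adjusted p = 3.01e-11). The cryptic junction ended 226 nt upstream of the cryptic polyadenylation site. A second cluster on the opposite strand listed the same 2 junctions, with 54.2 and -54.2 points in the authors' deposited table. It was the 1 cluster, of 508 in genes also in the 3' end-seq table, whose strand differed from that of the gene.

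**Figure D4:**
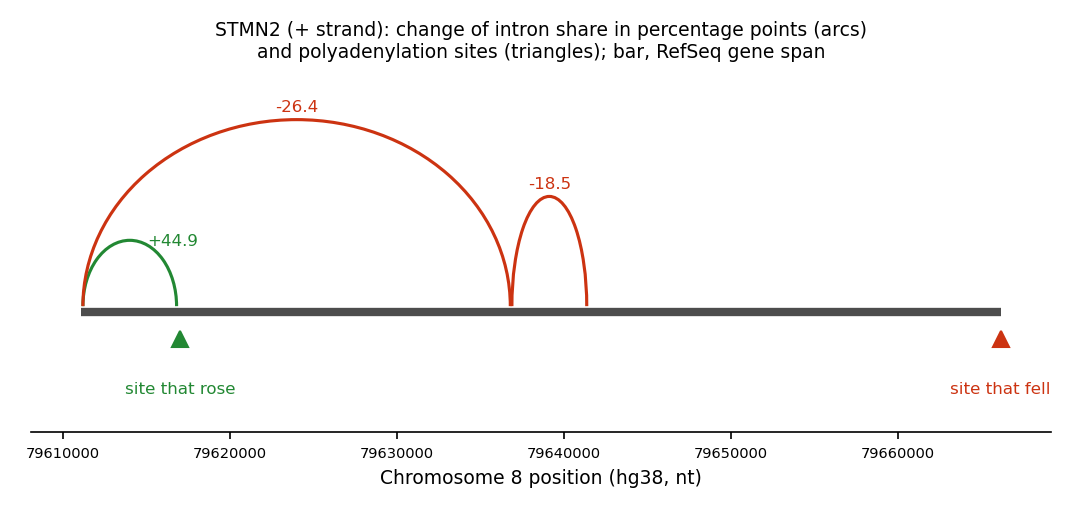
The map shows STMN2 on chromosome 8 (hg38, x axis in nucleotides, to scale), with the RefSeq gene span as a bar, 3 introns of the authors' deposited splicing table as arcs and the 2 sites of the authors' deposited 3' end-seq table as triangles. Numbers are changes of the intron share in percentage points; the cryptic junction gained 44.9 points and ends 226 nt before the site that rose.

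Splicing changed in many genes, at annotated and unannotated junctions. The authors' deposited LeafCutter tables, which group introns that share a splice site into clusters, listed 2994 clusters with 15980 introns in 2410 genes at an adjusted p of at most 0.05. The largest gains in the authors' deposited table were in NYNRIN at 91 percentage points, the phosphofructokinase gene PFKP at 79.7 and the insulin receptor gene INSR at 75.6. VDAC3 at 68.2, ARHGAP32 at 67.6, PRELID3A at 62.7, POLDIP3 at 57.5 and ADCY1 at 56.9 followed in the authors' deposited table. The largest losses in the authors' deposited table were in NYNRIN at -91 points, ADCY1 at -88.3, EPB41L4A at -87.1 and INSR at -85.6. PFKP at -79.7, SLC24A3 at -78, CACNA1E at -71.9 and CBARP at -71.7 came next in the authors' deposited table. Each adjusted p is that of a cluster, and the introns within it were not tested singly. The tables do not say which group was subtracted; a positive value is read here as a gain in the knockdown, because the STMN2 junction with a positive value leads to the site whose use the cryptic table gives as higher there.

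Of 33 genes reported elsewhere as splicing targets of TDP-43, 31 had a cluster in the authors' deposited table and 26 had an intron that changed by at least 10 points. The 2 not listed were ATG7 and MYO1C. UNC13A, which encodes a synaptic vesicle priming protein, gained 21.8 points at a cryptic 3' splice site between 17642541 and 17642845 on the minus strand of chromosome 19 in the authors' deposited table (cluster adjusted p = 0.00105). KALRN gained 31.7, HDGFL2 37.7, UNC13B 37.8, ACTL6B 50.7 and CAMK2B 29.8 points at cryptic junctions in the authors' deposited table. SYT7, a synaptotagmin gene, had the smallest adjusted p of all clusters at 6.41e-23, with a cryptic intron that gained 12 points in the authors' deposited table. Of the 30 targets with a cryptic intron, the largest cryptic change was a gain in 25; at a change of at least 10 points it was a gain in 21 of 22. RAP1GAP was the exception at that size, with a cryptic intron at -32.2 points in the authors' deposited table. Members of this list were known as targets beforehand, so they are not independent evidence.

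The authors' deposited table marked 2658 clusters (88.8%) as cryptic, meaning that they hold at least 1 unannotated junction. The mark gives the presence of such a junction, so it alone does not say that a cryptic junction changed. In 1746 of these clusters (65.7%) the largest change was in an annotated intron. That count does not separate clusters with a cryptic change from those without. In ADCY1 an annotated intron changed by -88.3 points and a cryptic intron of the same cluster by 56.9 points in the authors' deposited table. In CAMK2B these values were -65.6 and 29.8 points in the authors' deposited table. The median of the largest absolute change per cluster was 0.064, and 989 clusters had a change of at least 0.1 in intron share. A cryptic intron gained at least 0.1 in 252 clusters and at least 0.2 in 83. Among cryptic introns that changed by at least 0.1, 293 gained and 126 lost (69.9% gained, 95% exact binomial interval 65.3 to 74.3, p = 2.03e-16), against 441 and 657 annotated introns (40.2% gained; odds ratio 3.46, Fisher's exact p = 2.20e-25). Introns of a cluster sum to 0 and are not independent, and an intron with a low control share cannot lose 0.1.

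Splicing changes were counted in the gene groups fixed beforehand. Each value below is that of 1 intron of a cluster, annotated or not, so its sign is not that of a change in the gene. Of 31 presynaptic genes, 17 had a cluster and 8 had a change of at least 10 points in the authors' deposited table, among them SNAP91 at -22.2, RIMS1 at 18.1 and SNAP25 at -14.2 points. Among 27 postsynaptic glutamatergic genes 12 had a cluster, with SHANK1 at 39.9, GRIK2 at 20.9 and SHANK2 at 15.9 points in the authors' deposited table. The 27 ion channel genes had 12 with a cluster, including CACNA1C at -51.7, CACNA2D2 at -35.7 and KCND3 at -22.4 points in the authors' deposited table. Among 40 RNA-binding protein genes 18 had a cluster, with SFPQ at -15.4 and NOVA1 at 14.9 points in the authors' deposited table. A cryptic intron of the same SFPQ cluster gained 14.4 points in the authors' deposited table. Of the 34 ALS and FTD genes 6 had a cluster and 1, SQSTM1 at -14.9 points, changed by at least 10 points in the authors' deposited table. Of the 22 neuronal cytoskeleton genes 9 had a cluster and STMN2 alone changed by at least 10 points in the authors' deposited table. The cleavage and polyadenylation factors (4 of 25 with a cluster) and ribosomal protein genes (14 of 48) had no change of that size. These are counts without a test, because the genes that could be tested are not known here. The genes named are examples. Larger changes in these groups included CACNA1E at -71.9, CAMK2B at -65.6, UNC13B at -56.2 and CELF5 at -44.9 points in the authors' deposited table.

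The tables were also compared by direction of the 3' end-seq change. Genes called longer were also in the RNA-seq polyadenylation table in 220 of 1880 cases (11.7%) and genes called shorter in 14 of 339 (4.13%; odds ratio 0.325, two-sided Fisher's exact p = 7.72e-06, 1.16e-05 after adjustment over 3 such tests). Stratified by the distance between the sites, the odds ratio of an RNA-seq call was 0.424 (Mantel-Haenszel interval 0.242 to 0.745), weaker than without strata. Splicing clusters were found in 18.9% of longer and 19.5% of shorter genes, and no difference was detected (odds ratio 1.04, two-sided Fisher's exact p = 0.821). Among longer genes, the share also called in RNA-seq was lowest for the closest and the farthest pairs. It was 4.69% with sites up to 200 nt apart, 8.31% at 200 to 1000 nt, 16.2% at 1000 to 5000 nt, 15.5% at 5000 to 10000 nt and 5.26% at over 10000 nt.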

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

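Of 42 alternatives computed, 36 kept the direction and side of the threshold of the value given in the text, or stayed within 1.5 times of a count; those not planned beforehand were chosen after the data were seen. The share longer in 3' end-seq stayed between 84.7% and 85.6%, the share distal in RNA-seq between 95% and 96.3%, and the share of cryptic introns that gained between 55.3% (any change above 0) and 83.3% (at least 0.2). Counts moved by over 1.5 times in 5 cases, by construction, since fewer items pass. RNA-seq polyadenylation genes were 433 in place of 841 at an adjusted p of at most 0.001. Cryptic sites were 207 in place of 457 at a knockdown usage of at least 20%. Genes with a splicing change were 1246 in place of 2410 at an adjusted p of at most 0.01, 883 with an intron changed by at least 0.1, and 275 with at least 0.2. The odds ratio of a splicing cluster, shorter over longer, turned from 1.04 to 0.947 when stratified by distance (Mantel-Haenszel interval 0.698 to 1.28), with neither past the threshold; the cause was not tested. No paired analysis was possible because no table used here carries a value per replicate. For the same reason no replicate could be left out and no other split of the samples counted. Not run were all alternatives of gene expression and of its backgrounds, a stricter p for cryptic sites, for which the table used here holds no p, and counting by site, since each gene has 1 pair. The unknown depth limits how far a gene outside the tables can be read: absence from a table does not show that it did not change.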

Other observations

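The tests in this part were chosen after the results were seen, except the association of direction between the 2 assays, which the report also gives. Also not planned beforehand were the report's comparisons of shorter with longer genes and its test of cryptic introns that gained. Beyond the groups described in the report, housekeeping and stress genes appeared in small numbers. Those in the 3' end-seq table were all longer, which does not set them apart, since 84.7% of all genes there were longer. Of 30 lysosome genes 4 were longer, LAMP2 at 0.249, ATP6V1H at 0.135, SCARB2 at 0.127 and LAMP1 at 0.117 in the authors' deposited table. ATP6V1H, a subunit gene of the vacuolar proton pump, also had a cryptic site past its end that rose from 0.140% to 16.5% usage in the authors' deposited table. Of 24 cholesterol synthesis genes 3 were longer (MVD at 0.216, SC5D at 0.206 and MSMO1 at 0.203) and 10 had a splicing cluster in the authors' deposited tables. Of 24 integrated stress and unfolded protein response genes 4 were longer, including VLDLR at 0.251 and ATF3 at 0.230, and 2 had a splicing cluster, ASNS and HYOU1, in the authors' deposited tables. Of 24 p53 target genes 0 were in the 3' end-seq table, 2 were distal in RNA-seq (EDA2R at 1.09 and PHLDA3 at 0.975) and 3 had a splicing cluster in the authors' deposited tables. ISG15 at 0.481 was the 1 interferon-stimulated gene of 24 that any of the authors' deposited tables listed, and none of the 13 mitochondrially encoded genes was listed. The falling site of ISG15 lay before the start of its RefSeq gene.

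Markers of other cell types were counted in the same tables. No astrocyte (10), mesenchymal (14) or GABAergic neuron (10) marker was listed. Of the 15 pluripotency markers TERF1 had a splicing cluster at -6.6 points, and of 10 oligodendrocyte markers MBP had one at 29.6 points, in the authors' deposited table. Of 22 cycling markers CCNB1 was longer at 0.161, and of 17 neural progenitor markers ID2 was longer at 0.411 and FABP7 and NES had splicing clusters, in the authors' deposited tables. Of 12 peripheral neuron markers RET at 0.319 and POU4F1 at 0.146 were longer and 3 had splicing clusters in the authors' deposited tables. Of 16 cortical glutamatergic markers MEF2C was longer at 0.288, CUX1 was shorter at -0.394 and CUX2 had a splicing change of 31.1 points in the authors' deposited tables. These tables list changes in processing and not levels, so they do not measure how many cells of each type were present.

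Nearly all RNA-seq polyadenylation calls were distal, which could come from a difference in coverage of transcript 3' ends between the RNA-seq libraries. Such a difference would call genes distal whatever 3' end-seq found. Among the 14 shared genes that 3' end-seq called shorter, 50% were distal in RNA-seq, against 99.1% of the 220 called longer (Fisher's exact p = 1.68e-08). This argues against a coverage difference as the whole cause for the shared genes, whichever way the RNA-seq sign is read. A partial contribution is not excluded: 7 of the 14 were distal, while 2 of the 220 were proximal. For the 607 genes called by RNA-seq alone, 94.6% of them distal, no value used here decides, and the coverage difference and a longer transcript after TDP-43 loss cannot be told apart.

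Sites marked premature would be expected to shorten a gene, yet 34 of the 78 intronic sites paired in 3' end-seq belonged to genes called longer. A candidate explanation is that such a site lies past the RefSeq end of the gene it is named for, inside an intron of a longer model or a neighbour. That was so for 18 of the 34 sites, counting any distance past the end. They made up 62.1% of the 29 with a RefSeq gene. Of the 1753 other rising sites of genes called longer, 175 were past the end (9.98%, two-sided Fisher's exact p = 2.36e-11 over sites). At over 100 nt past the end the counts were 17 of 29 and 104 of 1753 (two-sided Fisher's exact p = 1.20e-13). Those 1753 are of other kinds, such as cryptic 3'UTR sites, with 77 inside and 7 past the end. The p-values thus compare kinds of site and do not test the explanation. Of the 34 intronic sites, 10 lay inside the RefSeq gene and 1 before its start, which the explanation does not cover. Another 5 had no RefSeq gene to check. Exonic sites are also marked premature, and 12 were paired in genes called longer against 6 in genes called shorter. Of the 12, 5 lay past the end, 5 lay inside and 2 had no RefSeq gene. No other explanation was examined.

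STMN2 raised the hypothesis that most intronic cryptic sites end a cryptic exon listed by LeafCutter. Of the 129 sites, 20 lay in a gene with a listed cluster, and a cryptic junction that gained ended up to 1000 nt upstream of 2 of the 20 (10%, 95% exact interval 1.23 to 31.7), in STMN2 and STAU2. The STAU2 junction ends at an annotated 3' splice site. Within 1000 nt, 1 of the 20, in STMN2, thus had the unannotated 3' splice site that a cryptic exon needs. In a window of 5000 nt, a gaining junction of that kind ended upstream of 2 of the 129 sites, in ARHGAP22 and STMN2, and downstream of 1. These counts argue against listed cryptic exons at most of the 20 sites. The other 109 sites lay in genes without a listed cluster or were assigned to no named gene. The table lists changed clusters only, so cryptic exons that it does not list stay open. A related hypothesis is that use of an intronic site goes with less splicing of the intron that holds it: 9 annotated introns held a site, and 8 of them (88.9%) lost share. The first version of this test counted sites, 9 of 10 (exact binomial p = 0.0215), but 2 STAU2 sites share an intron. Counted once per intron, the exact binomial p was 0.0391. Without STMN2, which had prompted the hypothesis, 7 of 8 lost (exact binomial p = 0.0703). Of all listed annotated introns, 57.1% lost share. Against that share the exact binomial p was 0.0878 with STMN2 and 0.149 without it, so the hypothesis stays open.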
